A study of Mus musculus with 18 samples.

How the data were processed

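Bone marrow-derived macrophages of C57BL/6 mice were grown for 7 days with 10 ng/ml M-CSF and 10% serum and stimulated for 18 h with 100 ng/ml LPS and 20 ng/ml interferon gamma (M1) or 20 ng/ml IL-4 (M2), per the labels' protocols. WT, PGRN knockout and myeloid 14-3-3ε knockout cells give 6 groups of 3 libraries, and all 18 columns of the table were matched to a sample. Per the submitters' processing notes, reads were aligned with STAR to GRCh38, quantified with RSEM 1.3.1 and normalized with DESeq2; the gene IDs are mouse IDs, so the build named there is not used here. The deposited values are log2 of a normalized count plus 1, per gene and library.

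The design, written before the data were examined, assumed counts; the file holds normalized log2 values, so the test laid down for that case was used. In each library the deposited log2 values turn back into whole multiples of a single step for 100% of genes, to within 0.1 of a read, and that step gave the recovered reads, the depth of each library and the size factors. Depth sets the precision: a read is worth 4.46 normalized counts in the shallowest library. Of 43309 gene IDs, 42425 were matched to GENCODE M21 on GRCm38 for names and positions; 124 symbols belong to several IDs, and the table has 0 genes of the mitochondrial genome, which were not analysed here.

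Genes with a normalized count of at least 1 in at least 3 libraries were tested, 21336 in all, with limma 3.58.1 in R 4.3.3 (trend and robust variance) on log2 of the normalized count plus 1, in a single fit of the 6 groups without further terms. The 9 comparisons were WT M1 with WT M2, each knockout with WT in each polarization, the knockouts with each other in each polarization, and the difference of each knockout's effect between M1 and M2. Adjusted p is Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures, and random steps used seed 1.

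The genes named are Grn and Ywhae, and those of a rule fixed in advance: among genes past the threshold whose 3 and 3 libraries do not overlap, with a mean of at least 5 CPM over the 2 groups and no predicted or clone name, the 8 largest rises and 8 largest falls of each of the first 5 comparisons and 5 and 5 of the others, and up to 4 members with the smallest p of each list described. Some genes of that rule are not reported here. Genes from lists that did not pass, and Lyz2 in M1, were chosen after their values were seen. For genes without a read in a group the fold is a lower bound that puts 3 reads in each library of that group.

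The 31 lists, also fixed in advance, were M1 markers, M2 markers, NF-kB targets, type I interferon response, interferon gamma response, MHC class II presentation, lysosome, cholesterol synthesis, LXR and lipid handling, glycolysis and HIF1, oxidative phosphorylation, cell cycle, complement, osteoclast, matrix and proteases, unfolded protein response, NRF2 and oxidative stress, inflammasome and cell death, TNF and progranulin pathway, 14-3-3 family, macrophage identity, Cre driver and strain checks, 7 lists of other cells (neutrophil, T and NK, B and plasma, dendritic, mast and basophil, erythroid and megakaryocyte, stroma), sex, and RNA quality. They were tested with camera (correlation 0.01, Benjamini-Hochberg over the lists of a comparison), with an estimated correlation (statmod 1.5.0) and with fry as alternatives, and members were also adjusted over the list alone. The overlap of the knockouts was set beside 100 simulations without effects, since they share WT libraries.

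Alternatives chosen in advance were a pseudocount of 0.1, no filter (26769 genes), at least 5 CPM in at least 3 libraries (11645 genes), only the groups compared in the fit, the replicate number as a block, each library left out in turn, and a threshold of 0.01 for the overlap. Added after the data were seen were precision weights (voom) on the recovered reads, thinning to the depth of the shallowest library (19679 genes), scaling by library totals, leaving out the 2 libraries rich in ribosomal RNA-like reads, and a covariate from the 13 stromal markers. On simulated data with 200 changed genes each, the first 5 comparisons recovered 95, 93, 92, 93 and 92% of 2-fold and 99, 100, 100, 100 and 100% of 4-fold changes. Unchanged genes passing were 63, 100, 44, 4 and 1, over the threshold's share of calls in the first 3. At equal depth they were 6, 4, 6, 8 and 7.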

Results

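The samples are mouse bone marrow-derived macrophages on a C57BL/6 background, grown with M-CSF and then driven to an M1 state with LPS and interferon gamma or to an M2 state with IL-4. Total RNA was sequenced from 3 genotypes: WT, a PGRN knockout (gene Grn, encoding progranulin) and a myeloid knockout of 14-3-3ε (gene Ywhae). Each of the 6 groups has 3 libraries, 18 in all, and the deposited table holds 43309 genes, of which 21336 were tested. Reads recovered per library, in units of M reads, were 5.16, 14.5 and 7.40 in WT M1, 11.8, 9.59 and 51.7 in PGRN knockout M1, and 105, 42.6 and 19.9 in 14-3-3ε knockout M1. In M2 they were 14.2, 30.6 and 21.8 in WT, 31.0, 58.8 and 13.7 in PGRN knockout, and 27.3, 16.9 and 21.3 in 14-3-3ε knockout. The deepest library has 20.4 times the reads of the shallowest. Ribosomal RNA-like genes took 14.3% of the reads of WT M2 replicate 3 and 1.85% of WT M1 replicate 2, against at most 0.208% in the others.

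Differences are given as log2 fold change ± standard error with n = 3 libraries per group, and levels as mean ± standard deviation of normalized counts. Genes named as the largest rises or falls have 3 and 3 libraries that do not overlap. Standard deviations cover the spread between libraries, and the lower bounds on folds cover counting error alone. The p-values measure only the spread between these samples, because whether the 3 libraries of a group come from separate mice or separate cultures is not given in the sources used here.

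Polarization separates the libraries first. Over 11645 well-measured genes the first component holds 60.4% of the variance and splits M1 from M2 in every genotype. The second, with 12.4%, puts PGRN knockout at one end and 14-3-3ε knockout at the other with WT between, and the third, with 9.96%, sets WT apart from both knockouts. Correlation between libraries of the same group was lowest in WT M1 (0.912 to 0.941) and highest in PGRN knockout M2 (0.984 to 0.986).

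**Figure D1:**
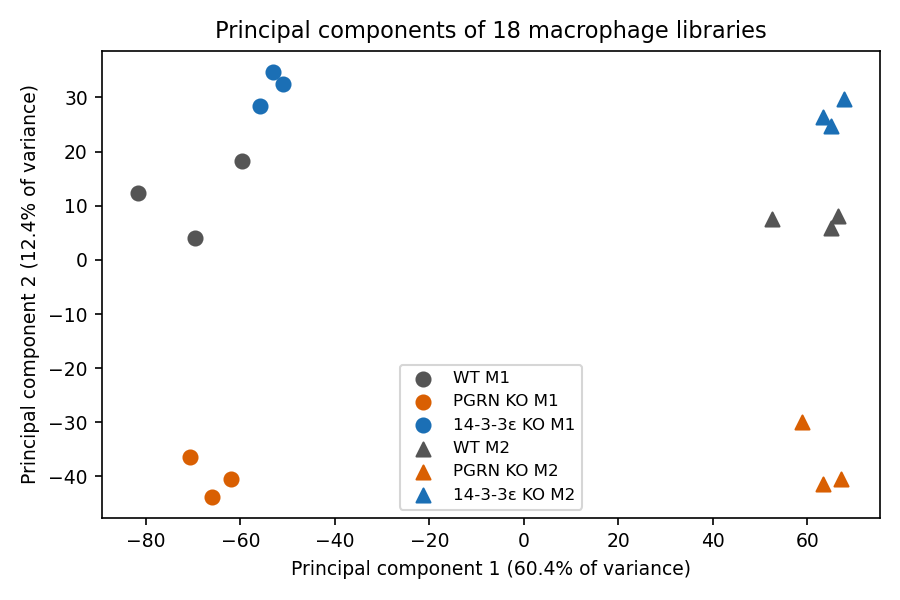
First and second principal components of log2 values, with 60.4% and 12.4% of the variance. Each point is a library; circles are M1 and triangles M2, grey WT, orange PGRN knockout and blue 14-3-3ε knockout.

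Grn is nearly absent from every PGRN knockout library. Grn, which encodes a secreted and lysosomal glycoprotein, stood at 497, 212 and 231 normalized counts in the PGRN knockout M1 libraries against 91070.0, 81989 and 91739 in WT M1. In M2 it stood at 24.4, 23.9 and 32.2 against 30086, 29365 and 34556. The fall was -8.24 ± 0.22 in M1 (adjusted p = 2.47e-12) and -10.14 ± 0.22 in M2 (adjusted p = 2.16e-13). In 14-3-3ε knockout Grn was 69306, 69903 and 66328 in M1 and 26971, 27845 and 26102 in M2, and its difference from WT did not pass (-0.36 ± 0.22, adjusted p = 0.263 in M1; -0.21 ± 0.22, adjusted p = 0.624 in M2).

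Ywhae, an adaptor that binds phosphorylated proteins, is lowered but not lost in the 14-3-3ε knockout. It was 6214, 5191 and 5537 in the knockout M1 libraries against 9859, 9021 and 9034 in WT M1, a fall of -0.72 ± 0.08 (adjusted p = 3.02e-05). In M2 it was 5088, 4362 and 5131 against 9015, 8203 and 8999 (-0.85 ± 0.08, adjusted p = 7.76e-06). The fall is 1.65-fold in M1 and 1.8-fold in M2. These gene-level values count reads from any exon and do not show which exons were deleted. In PGRN knockout Ywhae was 8542, 8815 and 8516 in M1 and 7949, 7432 and 7792 in M2 (not past: -0.11, adjusted p = 0.364; -0.18, adjusted p = 0.141). On GRCm38 with GENCODE M21, both protein-coding genes lie on the plus strand of chromosome 11, Ywhae at 75732869 to 75765845 and Grn at 102430315 to 102437048. Whether genes within 10 Mb of the targeted gene passed more often than others, among the 11645 well-measured genes less the target, is left open by Fisher's exact test. The shares around Grn were 43.1% against 37.9% in M1 (adjusted p = 0.264) and 38.3% against 32.0% in M2 (adjusted p = 0.246). Around Ywhae they were 33.3% against 32.4% in M1 and 11.2% against 10.4% in M2 (adjusted p = 0.784 for both).

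**Figure D2:**
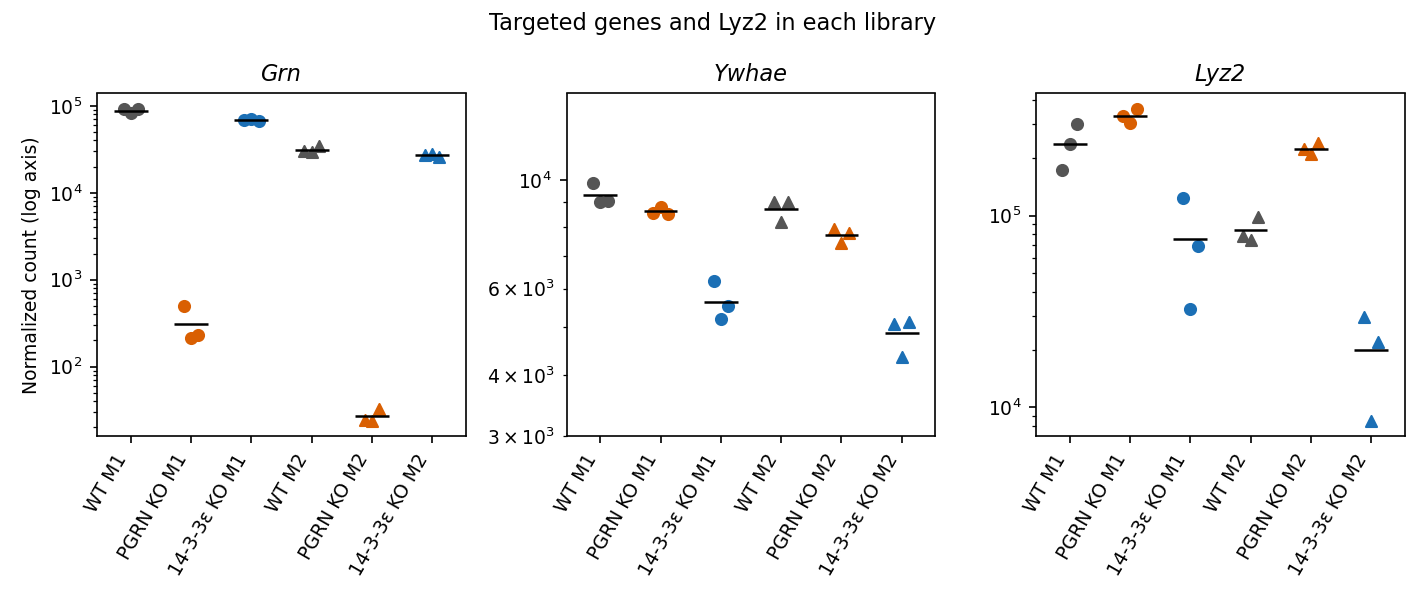
Normalized counts of Grn, Ywhae and Lyz2 in each library on a log axis, by group; points are libraries and bars group means. Grn falls to 313 and 26.8 on average in PGRN knockout, Ywhae falls 1.65-fold and 1.8-fold in 14-3-3ε knockout, and Lyz2 is lowest in 14-3-3ε knockout.

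In WT cells, M1 macrophages had higher M1 marker, interferon response and NF-kB target genes than M2 macrophages and lower M2 marker genes. Of 8303 genes past the threshold 4029 were higher and 4274 lower in M1, with 1938 and 1661 of them over 2-fold. Ccl5, a T cell-attracting chemokine, rose most, from 46.8 ± 36.4 to 98143 ± 15669 (11.31 ± 0.41). The Schlafen genes Slfn4 (10.27 ± 0.26) and Slfn1 (9.37 ± 0.29) rose with Pydc3 (9.76 ± 0.45), Ms4a4c (9.55 ± 0.42), the itaconate-producing enzyme gene Irg1 (9.36 ± 0.28) and the acute-phase gene Saa3 (9.35 ± 0.20; adjusted p = 4.68e-15 to 1.97e-10 for the 7). Ly6i, on 2 reads in M2, went from 0.545 to 1761. Retnla, a marker of alternative activation, fell from 54515 ± 7033 to 29.0 ± 21.1 (-11.11 ± 0.56, adjusted p = 1.69e-09). Without a read in M1 were the homeobox gene Msx3, down at least 62.2-fold from a mean of 560.0, the chitinase-like gene Chil4 (at least 44.7-fold), the tight-junction gene Cldn11 (at least 38.9-fold) and the potassium channel gene Kcnd3 (at least 26.4-fold; adjusted p = 1.29e-14 to 1.72e-10). Rnase2a, the sodium channel gene Scn3a and the E-cadherin gene Cdh1 had 2 reads each in M1 and means of 3147, 572 and 407 in M2. Grn itself was higher in M1 (1.496 ± 0.22, adjusted p = 4.84e-05), while Ywhae did not differ past the threshold (0.09 ± 0.08, adjusted p = 0.411).

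Among M1 markers 23 of 28 rose, 0 fell and 5 did not pass (24 and 0 adjusted over the list alone). The formyl peptide receptor gene Fpr2 9.04 ± 0.26 and Tnf 4.44 ± 0.15 were among them (camera adjusted p = 3.95e-18, adjusted p = 0.00285 with an estimated correlation). Among M2 markers 2 of 37 rose, 31 fell and 4 did not pass (3 and 31 adjusted over the list alone). The IL-4-induced factor gene Egr2 (-4.72 ± 0.14) and the dectin gene Clec7a (-3.68 ± 0.16) fell, and the IL-4 receptor gene Il4ra (2.87 ± 0.12) was higher in M1 (camera adjusted p = 1.36e-17, adjusted p = 0.00481 with an estimated correlation). Type I interferon response genes rose without exception, 33 of 33 (33 and 0 adjusted over the list alone), led by Oas3 (6.01 ± 0.12), Ifit2 (6.86 ± 0.14), Usp18 (6.01 ± 0.12) and the nucleic acid sensor gene Zbp1 (6.75 ± 0.14; camera adjusted p = 4.88e-45, adjusted p = 0.0078 with an estimated correlation). Ifnb1, without a read in M2, rose at least 14.2-fold. In the interferon gamma list 28 of 30 rose, 1 fell and 1 did not pass (28 and 1 adjusted over the list alone). The GTPase genes Irgm1 3.82 ± 0.09, Igtp 5.28 ± 0.15 and Irgm2 4.56 ± 0.14 and the peptide transporter gene Tap1 3.52 ± 0.08 were among them (camera adjusted p = 2.89e-24, adjusted p = 0.0153 with an estimated correlation). Of NF-kB targets 35 of 40 rose, 2 fell and 3 did not pass (36 and 2 adjusted over the list alone). The inhibitor gene Nfkbia 2.98 ± 0.08, Sod2 3.70 ± 0.12 and the chemokine gene Ccl3 3.66 ± 0.13 were among them (camera adjusted p = 4.06e-23, adjusted p = 0.000529 with an estimated correlation). Proliferation genes fell: in the cell cycle list 0 of 39 rose, 38 fell and 1 did not pass (0 and 38 adjusted over the list alone). The ribonucleotide reductase genes Rrm1 -1.29 ± 0.07 and Rrm2 -2.16 ± 0.14, Mcm2 -1.72 ± 0.11 and Ccne2 -2.70 ± 0.17 were among them (camera adjusted p = 3.33e-22, adjusted p = 0.0842 with an estimated correlation). Cholesterol synthesis genes fell with them, 22 of 25 and none the other way, with Hmgcs1 -1.38 ± 0.12, Sqle -2.09 ± 0.19 and Insig1 -1.66 ± 0.15 (0 and 22 adjusted over the list alone; camera adjusted p = 2.88e-11, adjusted p = 0.156 with an estimated correlation).

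Complement genes were higher in M1 for 12 of 15 and lower for 2, with Cfb 8.27 ± 0.31, C3 3.78 ± 0.20, C2 3.59 ± 0.25 and the integrin gene Itgax -4.36 ± 0.15 (12 and 2 adjusted over the list alone; camera adjusted p = 9.73e-06, adjusted p = 0.0153 with an estimated correlation). Among inflammasome and cell death genes 13 of 18 rose, 1 fell and 4 did not pass (14 and 1 adjusted over the list alone). Casp4 2.93 ± 0.09, Mlkl 2.86 ± 0.10, Casp1 1.85 ± 0.08 and Gsdmd 1.98 ± 0.09 were among them (camera adjusted p = 5.68e-09, adjusted p = 0.0181 with an estimated correlation). Among glycolysis and HIF1 genes 14 of 28 rose, 1 fell and 13 did not pass (15 and 1 adjusted over the list alone). Pfkfb3 1.63 ± 0.12 and Vegfa 1.15 ± 0.12 were up and Pfkp -1.23 ± 0.08 down (camera adjusted p = 0.00254, adjusted p = 0.156 with an estimated correlation). Among macrophage identity genes 14 of 20 rose, 3 fell and 3 did not pass (14 and 3 adjusted over the list alone). The Fc receptor gene Fcgr1 5.61 ± 0.12, Tlr2 3.797 ± 0.14 and Cd14 3.08 ± 0.17 were among them (camera adjusted p = 0.000166, adjusted p = 0.156 with an estimated correlation). Among TNF and progranulin pathway genes 13 of 23 rose, 4 fell and 6 did not pass (13 and 5 adjusted over the list alone). The progranulin receptor gene Sort1 -1.83 ± 0.11 and Traf2 1.28 ± 0.11 were among them (camera adjusted p = 0.00692, adjusted p = 0.0238 with an estimated correlation). Among T and NK cell genes 7 of 18 rose, 1 fell and 10 did not pass (8 and 1 adjusted over the list alone). Il7r -2.30 ± 0.26, Lck 2.15 ± 0.36 and Gzmb 3.39 ± 0.57 were among them (camera adjusted p = 0.0265, adjusted p = 0.52 with an estimated correlation).

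The other 18 lists did not pass in this comparison: MHC class II presentation (camera adjusted p = 0.823), lysosome (0.451), LXR and lipid handling (0.128), oxidative phosphorylation (0.508), osteoclast (0.926), matrix and proteases (0.508), unfolded protein response (0.128), NRF2 and oxidative stress (0.0947), the 14-3-3 family (0.508), Cre driver and strain checks (0.211), neutrophil (0.63), B and plasma cell (0.128), dendritic (0.917), mast and basophil (0.291), erythroid and megakaryocyte (0.78), stroma (0.451), sex (0.78) and RNA quality (0.508). Of these, the 14-3-3 family, lysosome, MHC class II, erythroid and megakaryocyte, and oxidative phosphorylation lists have a median, a mean and a camera direction that differ in sign. With only the WT groups in the fit 5218 genes passed.

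In M1 macrophages, loss of progranulin raised most members of the lysosome, LXR and lipid handling, and cholesterol synthesis lists. Of 5399 genes past the threshold 3039 were higher and 2360 lower, 673 and 985 over 2-fold. Hal, the histidine ammonia-lyase gene, rose most, from 8.95 ± 11.6 to 1027 ± 364 (7.32 ± 0.74, adjusted p = 1.15e-05). Cd4 (3.31 ± 0.50), the Rag GTPase gene Rragd (2.74 ± 0.18), which acts in amino-acid signalling to mTORC1, and the monoacylglycerol lipase gene Mgll (2.53 ± 0.17) rose too (adjusted p = 8.08e-08 to 0.00026). So did 4 serpin genes of a cluster of close copies, whose reads are hard to tell apart: Serpina3i (4.47 ± 0.32), Serpina3h (3.42 ± 0.31), Serpina3g (3.25 ± 0.36) and Serpina3f (2.85 ± 0.41; adjusted p = 1.41e-07 to 0.000165). After Grn, the largest falls were in Plac9a (-6.57 ± 1.04) and Plac9b (-4.24 ± 0.38), 2 near-identical copies, and Syn3 (-6.42 ± 1.38), which overlaps Timp3. The matrix protein genes Comp (-3.87 ± 0.27) and Mfap5 (-3.40 ± 0.25), the myosin gene Myo1h (-3.14 ± 0.66) and Eno1b (-4.66 ± 1.58), a copy of the enolase gene Eno1, fell as well (adjusted p = 1.17e-07 to 0.0476 for the 7).

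In the lysosome list 35 of 48 rose, 2 fell and 11 did not pass (38 and 2 adjusted over the list alone). The V-ATPase subunit gene Atp6v0d2 1.88 ± 0.11, the prosaposin gene Psap 1.33 ± 0.10 and the cathepsin gene Ctsb 0.96 ± 0.10 rose, and Grn is one of the 2 that fell (camera adjusted p = 1.65e-15, adjusted p = 0.158 with an estimated correlation). Of LXR and lipid handling genes 16 of 18 rose, 0 fell and 2 did not pass (17 and 0 adjusted over the list alone). The cholesterol exporter genes Abcg1 1.65 ± 0.09 and Abca1 1.44 ± 0.21, the fatty acid carrier gene Fabp5 1.79 ± 0.17 and Srebf1 0.47 ± 0.06 were among them (camera adjusted p = 4.19e-11, adjusted p = 0.042 with an estimated correlation). Cholesterol synthesis and uptake genes rose at the same time: 16 of 25 rose, 2 fell and 7 did not pass (18 and 2 adjusted over the list alone). Insig1 1.002 ± 0.15, Dhcr7 1.08 ± 0.17 and Nsdhl 0.80 ± 0.13 were among them (camera adjusted p = 1.11e-05, adjusted p = 0.522 with an estimated correlation). Among NRF2 and oxidative stress genes 12 of 18 rose, 2 fell and 4 did not pass (13 and 2 adjusted over the list alone). The autophagy receptor gene Sqstm1 1.04 ± 0.08, the catalase gene Cat 1.301 ± 0.13 and Srxn1 0.75 ± 0.09 were up and Me1 -0.89 ± 0.09 down (camera adjusted p = 8.27e-05, adjusted p = 0.325 with an estimated correlation). Among macrophage identity genes 9 of 20 rose, 3 fell and 8 did not pass (9 and 3 adjusted over the list alone). The efferocytosis receptor gene Mertk 1.88 ± 0.18, Cd68 1.07 ± 0.11 and Sirpa 0.56 ± 0.08 were among them (camera adjusted p = 0.0212, adjusted p = 0.522 with an estimated correlation). Glycolysis and HIF1 genes shifted down as a list: 2 of 28 rose, 9 fell and 17 did not pass (3 and 14 adjusted over the list alone). Bnip3 -1.04 ± 0.13 and Pfkl -0.65 ± 0.10 were down and Hk3 1.14 ± 0.12 and Pfkfb3 0.92 ± 0.12 up (camera adjusted p = 0.0118, adjusted p = 0.436 with an estimated correlation).

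Among interferon gamma response genes 11 of 30 rose, 0 fell and 19 did not pass (12 and 1 adjusted over the list alone). The PD-L1 gene Cd274 1.23 ± 0.13 and Irf8 0.82 ± 0.09 were among them (camera adjusted p = 0.000775, adjusted p = 0.522 with an estimated correlation). Among type I interferon response genes 10 of 33 rose, 0 fell and 23 did not pass (10 and 0 adjusted over the list alone). Ifit2 1.21 ± 0.14, Cmpk2 1.23 ± 0.16, Oas3 0.74 ± 0.12 and Trim30a 0.43 ± 0.08 were among them (camera adjusted p = 0.0104, adjusted p = 0.627 with an estimated correlation). Among inflammasome and cell death genes 10 of 18 rose, 0 fell and 8 did not pass (10 and 0 adjusted over the list alone). The DNA sensor gene Aim2 0.74 ± 0.08, Naip2 0.96 ± 0.12, Casp1 0.62 ± 0.08 and Naip5 0.84 ± 0.14 were among them (camera adjusted p = 0.00106, adjusted p = 0.41 with an estimated correlation). The Cre driver and strain list holds 5 genes, of which 3 rose, 0 fell and 2 did not pass, with Naip5, Casp4 0.35 ± 0.09 and Nlrp1b 0.70 ± 0.19 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0405, adjusted p = 0.436 with an estimated correlation).

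Markers of other cells moved too. Stromal genes shifted down as a list: 0 of 13 rose, 4 fell and 9 did not pass (0 and 7 adjusted over the list alone). Acta2 -1.396 ± 0.12, Cxcl12 -1.15 ± 0.25, Bgn -0.49 ± 0.12 and Sparc -0.53 ± 0.15 were among them (camera adjusted p = 0.000251, adjusted p = 0.436 with an estimated correlation). The collagen genes Col1a1, Col1a2 and Col3a1 together took 0.722 to 0.909% of reads in PGRN knockout libraries, 0.887 to 1.80% in WT and 1.64 to 2.48% in 14-3-3ε knockout, over both polarizations. Among B and plasma cell genes 0 of 12 rose, 3 fell and 9 did not pass (0 and 5 adjusted over the list alone). Ebf1 -0.88 ± 0.14, Ighm -2.04 ± 0.58 and Iglc2 -2.19 ± 0.72 were among them (camera adjusted p = 0.00251, adjusted p = 0.522 with an estimated correlation). The other 19 lists did not pass (camera adjusted p = 0.0623 to 0.823), M1 and M2 markers and NF-kB targets among them. In the 14-3-3 family, T and NK, and sex lists the median, mean and direction differ in sign. At equal depth 3462 genes passed and with only the 2 groups in the fit 2134. Under scaling by library totals the lower genes outnumber the higher (1820 and 2795), while Eno1b loses its call at equal depth and Syn3 under precision weights.

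In M1 macrophages, the 14-3-3ε knockout shifted 5 lists by camera, none of which passed with an estimated correlation. Of 4541 genes past the threshold 2554 were higher and 1987 lower, 701 and 422 over 2-fold. Chil1, a chitinase-like gene, rose from 26.0 ± 12.5 to 1529 ± 1278 (4.75 ± 1.05), and Cxcl13, a B cell chemokine gene, from 11.01 ± 6.24 to 282 ± 9.31 (4.68 ± 0.72). The interferon-induced gene Ifi44l had 1 read in WT M1 and a mean of 305 ± 264 in the knockout. Serpina3n (4.43 ± 0.62) and Lilra6 (4.24 ± 0.39) rose as well, and both belong to families of close copies (adjusted p = 4.32e-06 to 0.00746 for the 4). Rps3a3 (6.46 ± 0.58), Rps3a2 (5.31 ± 0.80) and Eno1b (5.20 ± 1.58) are copies of Rps3a1 and Eno1, so their rises (adjusted p = 1.05e-05 to 0.0354) cannot be placed at a given locus with certainty. Podoplanin (Pdpn, -3.78 ± 0.25), neuropeptide Y (Npy, -3.20 ± 0.42), androglobin (Adgb, -3.70 ± 0.38), Rpgrip1 (-4.88 ± 1.203), Syn3 (-4.80 ± 1.38), U90926 (-2.55 ± 0.39), the immunoglobulin gene Ighg2b (-3.24 ± 1.02) and the multi-copy gene Erdr1 (-4.99 ± 0.44) fell most (adjusted p = 1.1e-07 to 0.0406 for the 8).

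Among cell cycle genes 18 of 39 rose, 1 fell and 20 did not pass (23 and 1 adjusted over the list alone). The thymidylate synthase gene Tyms 0.87 ± 0.13, Rrm1 0.46 ± 0.07, Ccne2 1.08 ± 0.17 and Foxm1 0.70 ± 0.15 were among them (camera adjusted p = 8.76e-06, adjusted p = 0.958 with an estimated correlation). Among glycolysis and HIF1 genes 9 of 28 rose, 1 fell and 18 did not pass (12 and 1 adjusted over the list alone). The glucose transporter gene Slc2a1 0.55 ± 0.08, Hk1 0.47 ± 0.07, Pfkp 0.48 ± 0.08 and Gapdh 0.43 ± 0.08 were among them (camera adjusted p = 0.00865, adjusted p = 0.804 with an estimated correlation). Among oxidative phosphorylation genes 5 of 34 rose, 14 fell and 15 did not pass (6 and 18 adjusted over the list alone). Ndufb10 -0.69 ± 0.16, Ndufb3 -0.68 ± 0.17 and Cox5a -0.61 ± 0.16 were down and Idh3a 0.41 ± 0.08 up (camera adjusted p = 0.00244, adjusted p = 0.958 with an estimated correlation). Among lysosomal genes 1 of 48 rose, 14 fell and 33 did not pass (2 and 15 adjusted over the list alone). Gla -0.55 ± 0.09 and Cd63 -0.48 ± 0.10 were down and Sort1 0.65 ± 0.11 up (camera adjusted p = 0.00963, adjusted p = 0.958 with an estimated correlation). Among cholesterol synthesis genes 9 of 25 rose, 2 fell and 14 did not pass (13 and 3 adjusted over the list alone). Sqle 1.03 ± 0.19, Insig1 0.75 ± 0.15 and Stard4 0.70 ± 0.14 were among them (camera adjusted p = 0.0352, adjusted p = 0.958 with an estimated correlation).

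The other 26 lists did not pass (camera adjusted p = 0.0531 to 0.921), stroma with 5 of 13 higher and none lower among them. In the 14-3-3 family, complement, Cre driver and strain, interferon gamma, M2 marker, macrophage identity, and matrix and protease lists the median, mean and direction differ in sign. Lyz2, the macrophage lysozyme gene and 1 of the 5 genes of the Cre driver and strain list, fell (-1.82 ± 0.45, adjusted p = 0.0144), from 172932, 235900.0 and 299713 to 123842, 32601 and 69486. The count fell to 2751 without WT M1 replicate 1, 2981 without 14-3-3ε knockout M1 replicate 1, 2272 without its replicate 2, 2567 at equal depth, 2220 with a stromal covariate and 385 with only the 2 groups in the fit. Under precision weights lower genes outnumber higher ones (1586 and 2166), and Chil1, Ifi44l and Syn3 lose their calls, as do Eno1b, Rpgrip1 and Ighg2b in other settings.

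In M2 macrophages, loss of progranulin again raised most members of the lysosome, lipid handling and cholesterol synthesis lists. Of 4141 genes past the threshold 2370 were higher and 1771 lower, 458 and 445 over 2-fold. Hal rose from 4.6 ± 1.38 to 696 ± 339 (6.88 ± 0.74), Cd4 from 60.4 ± 32.0 to 899 ± 99.4 (3.99 ± 0.50), and the endolysosomal channel gene Mcoln3 from 24.8 ± 2.25 to 218 ± 32.4 (3.08 ± 0.24). Ccdc148 (4.17 ± 0.36), the GTPase-activating protein gene Tagap (2.93 ± 0.25) and the serpin copies Serpina3h (5.49 ± 0.31), Serpina3i (5.48 ± 0.32) and Serpina3f (3.56 ± 0.41) complete the 8 largest rises (adjusted p = 1.34e-08 to 7.03e-05). After Grn, podoplanin (Pdpn, -3.44 ± 0.25), the pannexin gene Panx3 (-3.49 ± 0.73), the citrate transporter gene Slc13a5 (-2.899 ± 0.49), Insc (-2.92 ± 0.50), Megf6 (-2.86 ± 0.31), Plac9b (-3.39 ± 0.38) and Pcdhgc4 (-4.27 ± 0.67), which shares exons with the other gamma protocadherins, fell most (adjusted p = 2.3e-07 to 0.00349).

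Among lysosomal genes 37 of 48 rose, 2 fell and 9 did not pass (39 and 2 adjusted over the list alone). The sulfatase gene Galns 1.05 ± 0.08, Atp6v0d2 1.398 ± 0.11 and Psap 1.08 ± 0.10 were among them (camera adjusted p = 5.83e-19, adjusted p = 0.0869 with an estimated correlation). Among LXR and lipid handling genes 15 of 18 rose, 0 fell and 3 did not pass (16 and 0 adjusted over the list alone). Abcg1 1.04 ± 0.09, the LXR gene Nr1h3 1.28 ± 0.14, Fabp5 1.37 ± 0.17 and Abca1 1.45 ± 0.21 were among them (camera adjusted p = 2.75e-11, adjusted p = 0.0419 with an estimated correlation). Among cholesterol synthesis genes 16 of 25 rose, 1 fell and 8 did not pass (19 and 1 adjusted over the list alone). Sc5d 1.01 ± 0.14, Nsdhl 0.87 ± 0.13, Dhcr7 1.08 ± 0.17 and Insig1 0.94 ± 0.15 were among them (camera adjusted p = 6.44e-08, adjusted p = 0.419 with an estimated correlation). Among cell cycle genes 0 of 39 rose, 20 fell and 19 did not pass (0 and 30 adjusted over the list alone). Rrm1 -0.54 ± 0.07, Tyms -0.69 ± 0.13, the mitotic regulator gene Cdc20 -0.88 ± 0.17 and Ube2c -1.23 ± 0.24 were among them (camera adjusted p = 1.37e-12, adjusted p = 0.396 with an estimated correlation). Among type I interferon response genes 13 of 33 rose, 2 fell and 18 did not pass (16 and 2 adjusted over the list alone). Oas3 1.32 ± 0.12, Trim30a 0.82 ± 0.08, Parp14 0.77 ± 0.11 and Cmpk2 1.11 ± 0.16 were among them (camera adjusted p = 6.06e-05, adjusted p = 0.539 with an estimated correlation). Among interferon gamma response genes 10 of 30 rose, 2 fell and 18 did not pass (10 and 2 adjusted over the list alone). Cd274 1.22 ± 0.13, Gbp9 2.01 ± 0.22 and Irf8 0.72 ± 0.09 were among them (camera adjusted p = 0.00955, adjusted p = 0.597 with an estimated correlation). Among inflammasome and cell death genes 8 of 18 rose, 2 fell and 8 did not pass (11 and 2 adjusted over the list alone). Naip2 0.95 ± 0.12, Nlrc4 1.01 ± 0.13 and Naip5 1.04 ± 0.14 were among them (camera adjusted p = 0.00101, adjusted p = 0.389 with an estimated correlation). Among macrophage identity genes 6 of 20 rose, 0 fell and 14 did not pass (7 and 0 adjusted over the list alone). Mertk 2.08 ± 0.18, Sirpa 0.68 ± 0.08, Cd68 0.65 ± 0.11 and Itgam 1.18 ± 0.23 were among them (camera adjusted p = 0.0126, adjusted p = 0.533 with an estimated correlation).

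Among MHC class II genes 3 of 13 rose, 0 fell and 10 did not pass (3 and 0 adjusted over the list alone). The transactivator gene Ciita 1.34 ± 0.45, Lgmn 0.86 ± 0.08 and Ctss 0.82 ± 0.13 were among them (camera adjusted p = 0.0284, adjusted p = 0.597 with an estimated correlation). Oxidative phosphorylation genes shifted down as a list although 1 of 34 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.674 with an estimated correlation). Neutrophil genes shifted down with 0 and 0 of 14 past (0 and 0 adjusted over the list alone, camera adjusted p = 0.0248, adjusted p = 0.597 with an estimated correlation). Of erythroid and megakaryocyte genes 0 of 10 rose and 2 fell, the platelet factor gene Pf4 -2.02 ± 0.15 among them (0 and 2 adjusted over the list alone, camera adjusted p = 0.0203, adjusted p = 0.419 with an estimated correlation). Among stromal genes 1 of 13 rose, 5 fell and 7 did not pass (1 and 5 adjusted over the list alone). Acta2 -1.02 ± 0.12, Col1a1 -0.83 ± 0.20 and Col1a2 -0.70 ± 0.18 were down and Pdgfra 0.53 ± 0.14 up (camera adjusted p = 0.00616, adjusted p = 0.539 with an estimated correlation). Of the Cre driver and strain genes 4 of 5 rose, 0 fell and 1 did not pass (4 and 0 adjusted over the list alone), Lyz2 (1.42 ± 0.45, adjusted p = 0.0428) among the rises (camera adjusted p = 0.00532, adjusted p = 0.219 with an estimated correlation).

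The other 17 lists did not pass (camera adjusted p = 0.0703 to 0.988). In the 14-3-3 family, M1 marker, M2 marker, matrix and protease, sex, and TNF and progranulin lists the median, mean and direction differ in sign. Within the M2 markers, Clec7a (1.39 ± 0.16) rose and Chil4 (-2.76 ± 0.30) fell. Without PGRN knockout M2 replicate 3 the count was 2752, and scaling by library totals gave 1739 higher and 1948 lower.

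In M2 macrophages, the 14-3-3ε knockout raised 14 of 33 type I interferon response genes and 7 of 13 MHC class II genes. Of 1427 genes past the threshold 709 were higher and 718 lower, 253 and 164 over 2-fold. The phosphodiesterase gene Gdpd3 rose from 9.65 ± 6.33 to 176 ± 22.3 (4.23 ± 0.34), Hal from 4.6 ± 1.38 to 495 ± 303 (6.25 ± 0.74), and Nov, which encodes the matricellular protein CCN3, from 111 ± 31.8 to 890.3 ± 258 (2.99 ± 0.41). The carboxylesterase gene Ces1g (3.28 ± 0.55), Lilra6 (3.28 ± 0.39) and the uncertain copies Eno1b (6.93 ± 1.58), Rps3a3 (6.01 ± 0.58) and Rps3a2 (3.01 ± 0.80) also rose (adjusted p = 1.19e-06 to 0.0439 for the 8). Pdpn (-3.79 ± 0.25), the matrix gene Spon2 (-2.88 ± 0.30), Npy (-2.78 ± 0.42), Lyz2 (-2.24 ± 0.45), the C5a receptor gene C5ar1 (-1.92 ± 0.34), the elongation factor gene Eef1a2 (-1.83 ± 0.32), and the multi-copy genes Rpl17 (-2.07 ± 0.47) and Erdr1 (-4.51 ± 0.44) fell most (adjusted p = 1.34e-07 to 0.0212). Lyz2 went from 78619, 75049 and 98318 to 29558, 8510.2 and 21932.

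Among type I interferon response genes 14 of 33 rose, 0 fell and 19 did not pass (16 and 1 adjusted over the list alone). Xaf1 2.47 ± 0.16, Mx2 1.87 ± 0.24, the RNA sensor gene Ddx58 0.72 ± 0.10 and Oas3 0.76 ± 0.12 were among them (camera adjusted p = 2.87e-11, adjusted p = 0.429 with an estimated correlation). Among MHC class II genes 7 of 13 rose, 1 fell and 5 did not pass (9 and 1 adjusted over the list alone). H2-Aa 2.21 ± 0.45, H2-Eb1 2.15 ± 0.46 and the transactivator gene Ciita 2.06 ± 0.45 were up and Lgmn -0.54 ± 0.08 down (camera adjusted p = 0.000191, adjusted p = 0.451 with an estimated correlation). The H2 genes are close relatives whose reads are hard to tell apart. Among interferon gamma response genes 4 of 30 rose, 0 fell and 26 did not pass (8 and 1 adjusted over the list alone). Irgm2 0.73 ± 0.14, Gbp9 1.06 ± 0.22, Gbp2 0.74 ± 0.17 and Gbp7 1.06 ± 0.26 were among them (camera adjusted p = 0.043, adjusted p = 0.773 with an estimated correlation). Among lysosomal genes 0 of 48 rose, 8 fell and 40 did not pass (1 and 11 adjusted over the list alone). Cd63 -0.48 ± 0.10, Atp6v1h -0.41 ± 0.08 and Neu1 -0.42 ± 0.09 were among them (camera adjusted p = 0.00117, adjusted p = 0.773 with an estimated correlation). Among NRF2 and oxidative stress genes 0 of 18 rose, 3 fell and 15 did not pass (0 and 9 adjusted over the list alone). The ferritin genes Fth1 -0.59 ± 0.12 and Ftl1 -0.60 ± 0.14 were among them (camera adjusted p = 0.000967, adjusted p = 0.429 with an estimated correlation). Oxidative phosphorylation genes shifted down as a list with 1 of 34 past, Cox7a2 -0.49 ± 0.14 (0 and 0 adjusted over the list alone; camera adjusted p = 0.000104, adjusted p = 0.769 with an estimated correlation). Among cell cycle genes 1 of 39 rose, 1 fell and 37 did not pass (1 and 0 adjusted over the list alone). Tyms 0.69 ± 0.13 was up and Pcna -0.33 ± 0.09 down (camera adjusted p = 0.0202, adjusted p = 0.806 with an estimated correlation). Among dendritic cell genes 2 of 13 rose, 0 fell and 11 did not pass (4 and 1 adjusted over the list alone). Flt3 2.27 ± 0.60 and Cd209a 1.61 ± 0.45 were among them (camera adjusted p = 0.0298, adjusted p = 0.429 with an estimated correlation).

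The other 23 lists did not pass (camera adjusted p = 0.0625 to 0.932). In the cholesterol synthesis, glycolysis, macrophage identity, osteoclast, B and plasma, RNA quality, and unfolded protein response lists the median, mean and direction differ in sign. The count was 671 without WT M2 replicate 1, 577 without WT M2 replicate 3, and 578, 717 and 694 without 14-3-3ε knockout M2 replicates 1, 2 and 3. At equal depth 793 genes passed, scaling by library totals gave 1210.0 higher and 319 lower, and the calls of Eno1b, Rps3a2, Rpl17, Lyz2, C5ar1, Ces1g and Eef1a2 are each lost in at least 1 setting.

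Set directly against each other in M1, 14-3-3ε knockout cells have most lysosome and lipid handling genes lower and most cell cycle, glycolysis and stromal genes higher than PGRN knockout cells. Of 5337 genes past the threshold 2676 were higher and 2661 lower in 14-3-3ε knockout, 1190.0 and 629 over 2-fold. Apart from Grn itself (7.88 ± 0.22, adjusted p = 9.74e-12), Cxcl13 was higher by 6.98 ± 0.72, and Ifi44l, without a read in PGRN knockout, by at least 60.9-fold. The copies Eno1b (9.86 ± 1.58) and Rps3a3 (6.67 ± 0.58) were higher too. Adgb (-4.25 ± 0.38), Npy (-4.16 ± 0.42), Serpina3i (-4.84 ± 0.32), Serpina3g (-3.43 ± 0.36) and Erdr1 (-4.50 ± 0.44) were lowest against PGRN knockout (adjusted p = 2.55e-08 to 0.000487 for the 8 with a fold). Ywhae was lower as well (-0.61 ± 0.08, adjusted p = 2.55e-05). Among lysosomal genes 2 of 48 rose, 37 fell and 9 did not pass (2 and 38 adjusted over the list alone). Atp6v0d2 -1.96 ± 0.11 and Psap -1.56 ± 0.10 were among them (camera adjusted p = 7.21e-20, adjusted p = 0.0749 with an estimated correlation). Among LXR and lipid handling genes 1 of 18 rose, 14 fell and 3 did not pass (1 and 14 adjusted over the list alone). Fabp5 -3.17 ± 0.17 and the lipid receptor gene Trem2 -2.02 ± 0.14 were among them (camera adjusted p = 6.72e-10, adjusted p = 0.0643 with an estimated correlation). Among cell cycle genes 27 of 39 rose, 2 fell and 10 did not pass (30 and 2 adjusted over the list alone). Rrm1 0.91 ± 0.07 and Tyms 0.91 ± 0.13 were among them (camera adjusted p = 1.8e-07, adjusted p = 0.631 with an estimated correlation). Among glycolysis and HIF1 genes 18 of 28 rose, 2 fell and 8 did not pass (19 and 2 adjusted over the list alone). The lactate transporter gene Slc16a3 1.11 ± 0.11 and Pdk1 0.93 ± 0.09 were among them (camera adjusted p = 2.64e-06, adjusted p = 0.0773 with an estimated correlation).

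Stromal genes were higher in 14-3-3ε knockout than in PGRN knockout in M1: 10 of 13 rose, 0 fell and 3 did not pass (10 and 0 adjusted over the list alone). Acta2 1.86 ± 0.12 and Sparc 1.09 ± 0.15 were among them (camera adjusted p = 2.14e-06, adjusted p = 0.265 with an estimated correlation). With stromal expression as a covariate 1384 genes passed. B and plasma cell genes shifted up as a list (2 higher, 0 lower, 10 not past, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.662 with an estimated correlation). Mast cell and basophil genes did so too (6 higher, 0 lower, 5 not past, 8 and 0 adjusted over the list alone, camera adjusted p = 0.00457, adjusted p = 0.631 with an estimated correlation).

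Part of the interferon-induced genes were lower in 14-3-3ε knockout M1 than in PGRN knockout M1. Of the type I list 1 of 33 rose, 11 fell and 21 did not pass (1 and 13 adjusted over the list alone), Cmpk2 -1.58 ± 0.16 among them (camera adjusted p = 7.79e-05, adjusted p = 0.631 with an estimated correlation). Of the interferon gamma list 1 of 30 rose, 11 fell and 18 did not pass (1 and 15 adjusted over the list alone), Cd274 -1.501 ± 0.13 among them (camera adjusted p = 4.42e-06, adjusted p = 0.466 with an estimated correlation). Cholesterol synthesis genes had 0 higher, 5 lower, 20 not past (0 and 5 adjusted over the list alone, camera adjusted p = 0.0253, adjusted p = 0.706 with an estimated correlation). Oxidative phosphorylation genes had 1 higher, 3 lower, 30 not past (1 and 2 adjusted over the list alone, camera adjusted p = 0.00405, adjusted p = 0.662 with an estimated correlation). NRF2 and oxidative stress genes had 1 higher, 11 lower, 6 not past (1 and 11 adjusted over the list alone, camera adjusted p = 1.57e-05, adjusted p = 0.192 with an estimated correlation). Inflammasome genes, Naip5 -1.53 ± 0.14 among them, had 2 higher, 9 lower, 7 not past (4 and 10 adjusted over the list alone, camera adjusted p = 0.000735, adjusted p = 0.265 with an estimated correlation). Macrophage identity genes had 4 higher, 9 lower, 7 not past (4 and 9 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.631 with an estimated correlation). The other 17 lists did not pass (camera adjusted p = 0.236 to 0.726). In the M1 marker, MHC class II, NF-kB, sex, TNF and progranulin, and unfolded protein response lists the median, mean and direction differ in sign. Scaling by library totals gave 3804 higher and 1392 lower, precision weights 3044 and 3475, and Ifi44l, at 305 ± 264 in 14-3-3ε knockout M1, loses its call with precision weights.

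In M2 the contrast between the knockouts took in most lysosome, lipid handling and cell cycle genes, as in M1, and most cholesterol synthesis genes. Of 3884 genes past the threshold 1768 were higher and 2116 lower in 14-3-3ε knockout, 661 and 576 over 2-fold. Besides Grn (9.93 ± 0.22, adjusted p = 2.97e-13), Gdpd3 (4.05 ± 0.34), Ces1g (3.95 ± 0.55) and the copies Eno1b (10.69 ± 1.58) and Rps3a3 (6.97 ± 0.58) were higher. The RNA-binding protein gene Igf2bp3 (-5.03 ± 0.69), Cd4 (-4.68 ± 0.50), Serpina3h (-5.13 ± 0.31), Serpina3i (-5.12 ± 0.32) and Erdr1 (-4.59 ± 0.44) were lower (adjusted p = 1.62e-08 to 0.00036 for the 9), and so was Ywhae (-0.67 ± 0.08, adjusted p = 1.42e-05). Among lysosomal genes 1 of 48 rose, 39 fell and 8 did not pass (2 and 41 adjusted over the list alone). Atp6v0d2 -1.87 ± 0.11 and Galns -1.38 ± 0.08 were among them (camera adjusted p = 6.81e-24, adjusted p = 0.0405 with an estimated correlation). Among LXR and lipid handling genes 0 of 18 rose, 11 fell and 7 did not pass (0 and 13 adjusted over the list alone). The lipid droplet gene Plin2 -1.46 ± 0.12 and Fabp5 -2.09 ± 0.17 were among them (camera adjusted p = 8.27e-12, adjusted p = 0.0351 with an estimated correlation). Among cholesterol synthesis genes 0 of 25 rose, 16 fell and 9 did not pass (0 and 20 adjusted over the list alone). Msmo1 -1.17 ± 0.17 and Tm7sf2 -1.12 ± 0.16 were among them (camera adjusted p = 6.29e-10, adjusted p = 0.322 with an estimated correlation). Among cell cycle genes 30 of 39 rose, 1 fell and 8 did not pass (32 and 1 adjusted over the list alone). Tyms 1.38 ± 0.13 and Cdc20 1.15 ± 0.17 were among them (camera adjusted p = 1.84e-17, adjusted p = 0.317 with an estimated correlation).

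Also lower in 14-3-3ε knockout M2 than in PGRN knockout M2 were NRF2 and oxidative stress genes such as Fth1 -1.34 ± 0.12 (1 higher, 11 lower, 6 not past, 1 and 12 adjusted over the list alone, camera adjusted p = 7.47e-05, adjusted p = 0.317 with an estimated correlation). The inflammasome list, with Naip5 -1.502 ± 0.14, was lower (2 higher, 7 lower, 9 not past, 3 and 8 adjusted over the list alone, camera adjusted p = 0.00479, adjusted p = 0.322 with an estimated correlation). So was the macrophage identity list, with Lyz2 -3.66 ± 0.45 (3 higher, 9 lower, 8 not past, 4 and 11 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.373 with an estimated correlation). Stromal genes such as Acta2 1.35 ± 0.12 were higher (7 higher, 0 lower, 6 not past, 7 and 0 adjusted over the list alone, camera adjusted p = 0.000296, adjusted p = 0.338 with an estimated correlation). The mast cell and basophil list, with Mcpt8 1.68 ± 0.44, was higher (2 higher, 0 lower, 9 not past, 6 and 0 adjusted over the list alone, camera adjusted p = 0.0077, adjusted p = 0.522 with an estimated correlation). The other 22 lists did not pass (camera adjusted p = 0.0867 to 0.943). In the interferon gamma, matrix and protease, T and NK, sex, and TNF and progranulin lists the median, mean and direction differ in sign. With the stromal covariate 2575 genes passed, and scaling by library totals gave 2843 higher and 1205 lower.

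The effect of progranulin loss differed between M1 and M2 for 267 genes, 100.0 with a higher and 167 with a lower effect in M1, 44 and 76 over 2-fold. Gpr65, an acid-sensing receptor gene, fell from 1180.3 ± 27.0 to 264 ± 30.3 in M2, against 1527 ± 42.6 and 1863 ± 285 in M1 (difference 2.44 ± 0.17). The complement gene Cfb (2.56 ± 0.44) and lipase gene Lipn (2.27 ± 0.48) also differed. The differences of Chil4 (2.76 ± 0.43) and Msx3 (2.03 ± 0.33) rest on M2, since neither has reads to speak of in M1. In the other direction were the cell fusion gene Dcstamp (-3.13 ± 0.63), Tagap (-2.32 ± 0.35), the glycerol phosphate dehydrogenase gene Gpd1 (-2.31 ± 0.41), the retinol carrier gene Rbp4 (-2.15 ± 0.42) and Serpina3h (-2.07 ± 0.44; adjusted p = 2.71e-06 to 0.0296 for the 10). Grn had a larger fall in M2 (1.901 ± 0.31, adjusted p = 0.00974), and Ywhae no difference past the threshold (0.07 ± 0.11, adjusted p = 0.853). Cell cycle genes had a higher effect in M1 by camera, with 1 of 39 past, Tpx2 0.89 ± 0.21 (1 and 0 adjusted over the list alone, camera adjusted p = 2.78e-10, adjusted p = 0.788 with an estimated correlation). So had NRF2 and oxidative stress genes, with 1 of 18 past, Sqstm1 0.78 ± 0.11 (7 and 1 adjusted over the list alone, camera adjusted p = 0.000374, adjusted p = 0.585 with an estimated correlation). The other 29 lists did not pass (camera adjusted p = 0.051 to 0.969). In the complement, macrophage identity and sex lists the median, mean and direction differ in sign.

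That count for PGRN knockout, 267, was 659 without WT M1 replicate 1, 131 and 135 without PGRN knockout M1 replicates 1 and 3, 157 without WT M2 replicate 2, and 131, 147 and 100.0 without PGRN knockout M2 replicates 1, 2 and 3. It was 112 at equal depth and 93 with only the 4 groups in the fit; Gpr65 and Tagap kept their calls whichever library was left out, while Chil4, Lipn, Msx3, Dcstamp, Gpd1, Rbp4, Serpina3h and Grn each lose theirs at equal depth or with precision weights.

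The effect of the 14-3-3ε knockout differed between M1 and M2 for 61 genes, 30.0 higher and 31 lower in M1, 13 and 22 over 2-fold. Cxcl11, an interferon-induced chemokine gene with 2 reads in WT M2, differed by 2.99 ± 0.50, from 397 ± 152 to 2169 ± 439 in M1, so the difference rests on M1. The heme-binding protein gene Hebp1 (1.69 ± 0.17), the citrullinating enzyme gene Padi2 (1.35 ± 0.23), the LPS co-receptor gene Cd14 (1.26 ± 0.23) and Itgax (1.13 ± 0.21) followed. Hebp2 (-2.04 ± 0.29), Apol9a (-1.99 ± 0.37), Nxpe5 (-1.69 ± 0.30) and the chemokine gene Ccl4 (-1.63 ± 0.26) differed the other way (adjusted p = 0.000137 to 0.0323 for the 9). Neither Ywhae (0.13 ± 0.11, adjusted p = 0.779) nor Grn (-0.15 ± 0.31, adjusted p = 0.923) differed past the threshold. The type I interferon list had a lower effect in M1, with 1 of 33 past, Xaf1 -1.25 ± 0.23 (0 and 18 adjusted over the list alone, camera adjusted p = 5.79e-22, adjusted p = 0.217 with an estimated correlation). Glycolysis genes had a higher one, with 2 of 28 past, Pfkp 0.58 ± 0.11 and Slc2a1 0.58 ± 0.11 (3 and 0 adjusted over the list alone; camera adjusted p = 6.19e-05, adjusted p = 0.217 with an estimated correlation).

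Without a member past the threshold over all genes, 7 more lists differed by camera in the 14-3-3ε knockout effect. Higher in M1 was the cholesterol synthesis list (0 and 0 adjusted over the list alone, camera adjusted p = 6.19e-05, adjusted p = 0.59 with an estimated correlation). So was the cell cycle list (1 and 0 adjusted over the list alone, camera adjusted p = 0.000626, adjusted p = 0.949 with an estimated correlation). The NRF2 and oxidative stress list followed (0 and 0 adjusted over the list alone, camera adjusted p = 0.00644, adjusted p = 0.476 with an estimated correlation), and the 14-3-3 family (0 and 0 adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.31 with an estimated correlation). Lower in M1 was the interferon gamma response list (0 and 0 adjusted over the list alone, camera adjusted p = 8.22e-05, adjusted p = 0.554 with an estimated correlation). So was the MHC class II list (0 and 0 adjusted over the list alone, camera adjusted p = 0.000626, adjusted p = 0.476 with an estimated correlation), and the RNA quality list (0 and 1 adjusted over the list alone, camera adjusted p = 0.0054, adjusted p = 0.31 with an estimated correlation). The other 22 lists did not pass (camera adjusted p = 0.108 to 0.971). In the complement, Cre driver and strain, lysosome, macrophage identity, NF-kB, osteoclast, B and plasma, erythroid, and sex lists the median, mean and direction differ in sign.

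That count for 14-3-3ε knockout, 61, was 192 without WT M1 replicate 2, 27 without WT M1 replicate 3, 27, 17 and 23 without the knockout M1 replicates 1, 2 and 3, 9, 23 and 24 without the WT M2 replicates, and 20.0, 9 and 37 without the knockout M2 replicates. It was 27 at equal depth, 15 with precision weights, 37 under library totals, 120.0 without the 2 libraries rich in ribosomal RNA-like reads and 8 with only the 4 groups in the fit; Hebp1 kept its call whichever library was left out, while Cxcl11, Padi2, Cd14, Itgax, Hebp2, Apol9a, Nxpe5, Ccl4, Xaf1, Pfkp and Slc2a1 each lose theirs at equal depth, with precision weights or with the replicate block.

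The knockouts share more genes past the threshold in the same direction than independent lists would. In M1, 934 genes were higher in both, 532 lower in both and 404 opposite, where independence gives 364, 219.8 and 566. In M2 there were 250.0, 186 and 151 against 78.8, 59.6 and 139. Both knockouts are set against the same 3 WT libraries, so the lists are not independent. Their fold changes correlate with r = 0.52 in M1 and 0.47 in M2, where 100 simulations without any effect give 0.50 and 0.50 from the shared controls alone. The covariance is 0.363 in M1 and 0.242 in M2 against 0.125 and 0.124 simulated, at most 0.135 in either. The simulations draw each gene by itself, so they leave out deviations of a WT library that run through many genes, and how much of the excess of 0.238 and 0.118 comes from the shared WT libraries is not known. Hal, at 4.6 ± 1.38 in WT M2, is higher in both knockouts in M2 against that same low level. Leaving out WT M1 replicate 1 gave 723 shared genes in M1 in place of 1466 and replicate 2 gave 2906. In M2 leaving out WT M2 replicates 1 and 3 gave 185 and 176 in place of 436.

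Across polarizations each knockout repeated much of its own effect. PGRN knockout had 1574 genes higher in both M1 and M2, 2575 in the same direction in all and 35 opposite, where independence gives 338 higher and 514 opposite. For 14-3-3ε knockout 474 genes were higher and 459 lower in both and 3 opposite, against 84.9, 66.9 and 152. These pairs share no library, but whether same-numbered M1 and M2 libraries come from the same mice is not given in the sources used here.

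The levels of M1-type and M2-type genes lie closer together in 14-3-3ε knockout M1 than in WT M1. The M2-type minus M1-type score was -2.76, -2.39 and -2.51 in WT M1, -2.11, -2.24 and -2.23 in 14-3-3ε knockout M1 and -2.48, -2.60 and -2.43 in PGRN knockout M1. In M2 libraries it was 2.22, 2.54 and 2.50 in WT, 2.37, 2.45 and 2.51 in 14-3-3ε knockout and 2.52, 2.23 and 2.41 in PGRN knockout. With classes set between the WT groups, 112 of 1938 M1 genes rose and 481 fell in 14-3-3ε knockout M1 (median -0.31), and 536 of 1661 M2 genes rose and 45 fell (0.50). These classes share the WT M1 libraries with the comparison. For PGRN knockout M1 the counts were 307 and 411 (-0.14) and 452 and 120 (0.34), for PGRN knockout M2 358 and 142 (0.14) and 266 and 225 (-0.04), and for 14-3-3ε knockout M2 152 and 72 (0.07) and 46 and 65 (0.04). With classes set in PGRN knockout cells, which share no library with the comparison, 96 of 1057 M1-type genes rose and 266 fell in 14-3-3ε knockout M1 (median -0.17), and 370.0 of 1026 M2-type genes rose and 56 fell (0.35). With classes set in 14-3-3ε knockout cells, PGRN knockout M1 had 286 and 153 of 996 and 236 and 86 of 736, and the 2 median fold changes differ by 0.0352. In PGRN knockout M2 the same classes had 315 and 99 of 996 and 181 and 136 of 736, and the M2-type median fold change lies -0.19 from the M1-type median (-0.33 to -0.12 with any library left out). In 14-3-3ε knockout M2, with classes set in PGRN knockout cells, the medians differ by 0.11 (0.0134 to 0.16). All classes were chosen after the data were seen.

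**Figure D3:**
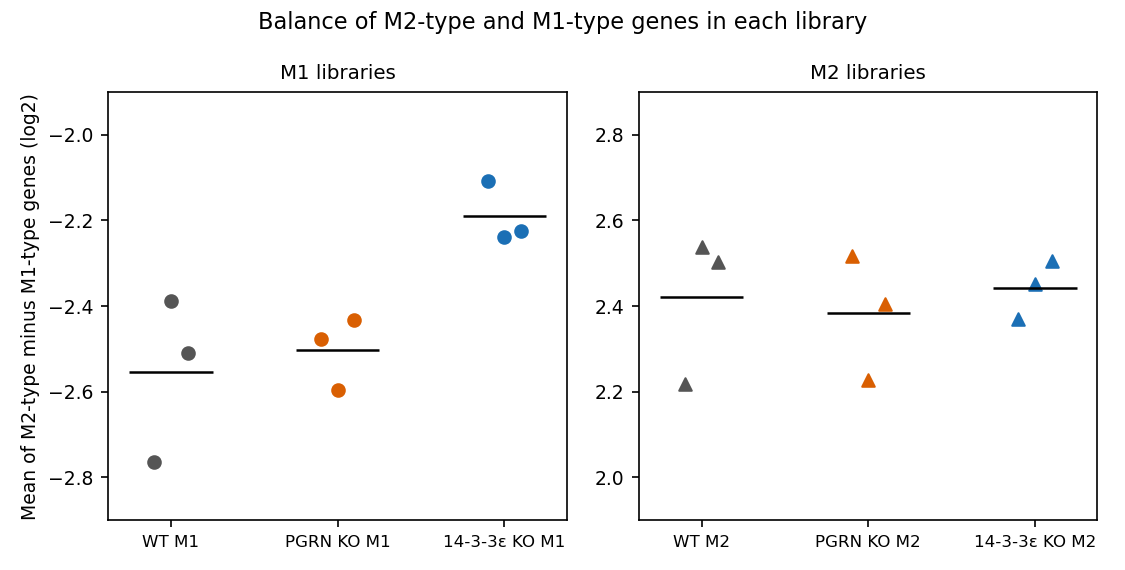
Mean log2 value of 588 M2-type genes minus that of 848 M1-type genes in each library, for M1 (left) and M2 libraries (right); bars are group means. The 14-3-3ε knockout M1 libraries (-2.24 to -2.11) all lie above the WT M1 libraries (-2.76 to -2.39).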

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

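The comparisons in this part between M1 and M2 effects were set before the data were examined; the tests that weigh explanations were chosen after the result was seen. What marked each result out is a difference between M1 and M2 in the effect of the same knockout.

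For PGRN knockout 267 genes differed. Higher in M1 were Chil4 2.76, Cfb 2.56, Gpr65 2.44, Lipn 2.27, Msx3 2.03, Grn 1.901, Tgfbi 1.74, Chac1 1.45, Klf4 1.37, Trib3 1.25, Cd40 1.22, Isg20 0.99, Tpx2 0.89, Sqstm1 0.78, Socs3 0.71, Sdhb 0.69, Sesn2 0.62 and Abcg1 0.61. Lower were Timp2 -0.60, Mmp19 -0.67, Socs2 -0.95, Egr2 -0.96, Ndrg1 -1.06, Adamts5 -1.51, Serpina3h -2.07, Rbp4 -2.15, Gpd1 -2.31, Tagap -2.32 and Dcstamp -3.13. Of 100 ways to split the libraries within each polarization, 7 gave as many genes, the real one and 6 of the 18 that keep genotype in 1 polarization and mix it in the other, with 1683 genes at the highest. Those 18 carry the knockout effect itself, so these splits leave chance undecided. The 81 mixed in both gave at most 4 genes.

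For 14-3-3ε knockout 61 genes differed. Higher in M1 were Cxcl11 2.99, Hebp1 1.69, Padi2 1.35, Cd14 1.26, Itgax 1.13, Nlrc4 1.03, Tnfaip2 0.61, Slc2a1 0.58 and Pfkp 0.58. Lower were Csf3r -0.70, Il4ra -0.97, Xaf1 -1.25, Apoc2 -1.32, Ccl4 -1.63, Nxpe5 -1.69, Apol9a -1.99 and Hebp2 -2.04. Of these only Hebp1 and Il4ra keep their calls at equal depth, with precision weights and with the replicate block alike. Of 100 splits 5 gave as many genes, the real one and 4 of the 18 true to genotype in 1 polarization, with 419 at the highest, which leaves chance undecided for the same reason. The 81 mixed in both gave at most 1 gene, which again says nothing about chance.

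In the other comparisons 10 splits of the 6 libraries are too few for a share under 0.05, and only 1 of 10 gave as many genes, the real one. Every other split mixes the 2 groups, so the real difference widens the spread within groups and few genes can pass. The values below therefore say nothing about chance. The real and highest other values are 8303 and 83 for WT M1 with WT M2, 5399 and 21 for PGRN knockout in M1, 4541 and 2 for 14-3-3ε knockout in M1, 4141 and 1 for PGRN knockout in M2, 1427 and 2 for 14-3-3ε knockout in M2, and 5337 and 1 in M1 and 3884 and 2 in M2 for the knockouts with each other.

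In M1 the genes that M2 cells express more stood above those that M1 cells express more in both knockouts. Shared WT M1 libraries could produce this, since they both set the classes and are the control. With classes from the other knockout the median gap shrinks to 0.0352 for PGRN knockout (0.0493 at equal depth, 0.0976 with the stromal covariate), under the 0.1 taken as no gap. For 14-3-3ε knockout it stays at 0.52 (0.50 at equal depth, 0.43 with the covariate, 0.39 to 0.61 with any library left out). This argues against depth and class choice as its whole cause. WT M1 stays the control and the covariate uses within-group spread, so controls and stroma stay open. The gap is not read here as a weaker M1 state, since 5 of 28 M1 markers rose there and 1 fell, Cxcl11 2.49 ± 0.35 and Il1b 1.15 ± 0.28 among the rises (camera adjusted p = 0.369, adjusted p = 0.958 with an estimated correlation). What sets the wide classes apart stays open.

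Lyz2 is lower in 14-3-3ε knockout. A smaller share of macrophages would lower the other 18 macrophage identity genes too, but their median is 0.16 in M1 and 0.00779 in M2, and 0 of 18 is as low as Lyz2. Reads shared with its copy Lyz1 could move between the genes, but the sum of Lyz1 and Lyz2 is still -1.77 ± 0.47 in M1 and -2.18 ± 0.47 in M2. A Cre gene inserted at Lyz2, a common way to delete a gene in myeloid cells, would lower Lyz2 itself and stays possible; the driver is not given in the sources used here.

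Stromal markers shifted down as a list in PGRN knockout, but not with an estimated correlation (adjusted p = 0.436 and 0.539); in 14-3-3ε knockout the list did not pass, with 5 of 13 higher in M1 and 2 in M2. A changed share alone, alike for all stromal cells, would move the 13 markers together. In M1, 3 markers lie over 2 standard errors from the list median in PGRN knockout (median -0.52, from Acta2 -1.40 to Pdgfra -0.15) and 3 in 14-3-3ε knockout (0.46, from Lum -0.95 to Pdgfrb 0.74). In M2, 4 markers lie that far in PGRN knockout (-0.56, from Acta2 -1.02 to Pdgfra 0.53) and 4 in 14-3-3ε knockout (0.33, from Lum -1.20 to Pdgfrb 0.76). The share of stromal cells stays undecided in M1 and M2, as error in the list median is not counted. No biological explanation was tested.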

How the results depend on the processing

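The alternatives named as added were chosen after the results were seen, the others planned. No single-gene result reversed in the settings run for it; lists were run in 3 settings, and the balance of higher and lower genes did turn in some. Of 134 single-gene and 155 list results, the call was kept by 127 under a pseudocount of 0.1 (7 lost), 133 without a filter (1), 131 under the strict filter (0), 112 with only the groups compared (22), 116 at equal depth (18), 117 with precision weights (16, 1 gained), 132 under library totals (2), 124 without the ribosomal RNA-rich libraries (10), 129 with the stromal covariate (5), and in 830 of the single-library tests (118). With an estimated correlation 42 list calls were lost: passing lists fell from 13, 12, 5, 14 and 8 to 8, 1, 0, 1 and 0 in the first 5 comparisons. Fry kept 125 (10 lost, 20 gained).

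Counts that moved by over 1.5 times are these; the cause was not tested. With only the groups compared: 5218 for WT M1 with WT M2 (main 8303), 2134 for PGRN knockout in M1 (5399), 385 for 14-3-3ε knockout in M1 (4541), 93 for the PGRN difference (267) and 8 for the 14-3-3ε difference (61), while it rose to 4652 for PGRN knockout in M2 and to 6255 in M1 and 5326 in M2 for the knockouts with each other. At equal depth: 3462 for PGRN knockout in M1, 2567 for 14-3-3ε knockout in M1, 793 for 14-3-3ε knockout in M2 (1427), 112 and 27 for the differences. With the stromal covariate: 2220.0 for 14-3-3ε knockout in M1, and 1384 in M1 (5337) and 2575 in M2 (3884) for the knockouts with each other. The 14-3-3ε difference had 15 genes with precision weights, 37 under library totals and 120.0 without the ribosomal RNA-rich libraries.

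The overlap in M1 (1466) was 348 at a threshold of 0.01, 733 at equal depth, 897 with precision weights, 2942 without the ribosomal RNA-rich libraries and 803 with the stromal covariate. In M2 (436) it was 85 at 0.01, 234 at equal depth and 782 with precision weights.

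With single libraries left out, the counts ran from 2272 to 6458 for 14-3-3ε knockout in M1, 2752 to 3725 for PGRN knockout in M2 (4141), 577 to 1650.0 for 14-3-3ε knockout in M2, 100.0 to 659 and 9 to 192 for the differences, and 723 to 2906 and 176 to 587 for the overlaps in M1 and M2. They ran from 7248 to 8932 for WT M1 with WT M2, 3887 to 6385 for PGRN knockout in M1, and 4120.0 to 4756 in M1 and 2785 to 3599 in M2 for the knockouts with each other. Grn ran from -8.63 to -8.02 in M1 and -10.28 to -10.07 in M2 in PGRN knockout, and Ywhae from -0.79 to -0.66 and -0.89 to -0.77 in 14-3-3ε knockout. Grn in 14-3-3ε knockout M1 passes with precision weights (adjusted p = 0.042).

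Library totals moved the median of all genes to -0.195, 0.128, 0.111, 0.191 and 0.143 in WT M1 with WT M2, 14-3-3ε knockout in M1 and in M2, and the knockouts with each other in M1 and M2; precision weights moved it to 0.156 and -0.113 in the first 2 of these. Higher and lower genes were then 2851 and 5487 (main 4029 and 4274) for WT M1 with WT M2 with 4042 and 3506 under precision weights, 1820.0 and 2795 (3039 and 2360.0) for PGRN knockout in M1, 2964 and 1215 (2554 and 1987) for 14-3-3ε knockout in M1 with 1586 and 2166 under precision weights, 1739 and 1948 (2370.0 and 1771) for PGRN knockout in M2, and 1210.0 and 319 (709 and 718) for 14-3-3ε knockout in M2. For the knockouts with each other they were 3804 and 1392 (2676 and 2661) in M1 and 2843 and 1205 (1768 and 2116) in M2, and for the 14-3-3ε difference 10.0 and 27 (30.0 and 31), with 5 and 10.0 under precision weights.

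With the replicate number as a block the 9 counts were 8379, 5496, 4716, 4356, 1616, 5448, 3986, 282 and 49. The block kept 131 single-gene (3 calls lost) and 152 list outcomes (1 lost, 2 gained). It spans genotypes, so it leaves pairing of M1 with M2 in each open. Only 14-3-3ε knockout M1 and M2 have same-numbered libraries deviating together throughout (0.53, 0.40 and 0.43), but Xist also ranks WT replicates alike in both. The design gives neither. The planned Wald test and second normalization on counts were not run: the file holds normalized values. Recovered reads went into voom and thinning only. Depth limits the weakly expressed genes most: the shallowest library has 5157638 reads, and 3 reads in each WT M1 library average 9.01 normalized counts.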

Other observations

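Apart from Nlrp1b in PGRN knockout, the results in this part were picked after their values were seen, out of comparisons set before. No cause was tested. In 14-3-3ε knockout, 2 of 4 genes that differ between mouse strains were higher than in WT: the inflammasome sensor gene Nlrp1b (2.98 ± 0.19 in M1, 2.37 ± 0.19 in M2; adjusted p = 5.61e-08 and adjusted p = 1.1e-06) and the transhydrogenase gene Nnt (0.70 ± 0.13 and 0.54 ± 0.13; adjusted p = 0.00254 and adjusted p = 0.026). Naip5 was lower in M1 (-0.69 ± 0.14, adjusted p = 0.00344) and not past in M2 (adjusted p = 0.0547), and Casp4 lower in M1 (-0.28 ± 0.09, adjusted p = 0.0356). In PGRN knockout Nlrp1b was higher too (0.70 ± 0.19 in M1, 0.70 ± 0.19 in M2). Lyz1 was higher in 14-3-3ε knockout (1.52 ± 0.31 and 1.74 ± 0.31).

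Xist stood at 1302, 39.1 and 6.10 normalized counts in WT M1 replicates 1 to 3 and 963, 52.6 and 2.06 in M2. In 14-3-3ε knockout it was 1306 and 3123 in M1 and M2 replicate 2 and 26.5 and 67.0 in replicate 3. In PGRN knockout it was at most 4.09. Replicate 1 of WT and 2 of 14-3-3ε knockout had the most Xist and least of the Y gene Ddx3y in M1 and M2. Ddx3y was 183 against 628 and 628 in WT M1 and 350 against 848 and 965 in M2. In 14-3-3ε knockout it was 389 against 782 and 848 in M1 and 423 against 1019 and 1073 in M2. The sex list joins Xist with Y genes moving oppositely, so it cannot test sex across genotypes.

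Il12b had 3 reads in WT M1, with a mean of 2.49, against 19.8 in PGRN knockout M1 and 20.6 in 14-3-3ε knockout M1.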
